A study of Danio rerio with 12 samples.

How the data were processed

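Regenerating caudal fin tissue of AB strain zebrafish larvae was profiled on 12 Affymetrix zebrafish arrays. Per the labels, fins were amputated at 2 days post fertilization, the larvae were kept for 1 h in water with DMSO (vehicle) or 0.5 ng/mL TCDD, and the regrown tissue was collected at 2 or 3 days post amputation (dpa). Each array holds RNA from a pool of 150 fins, with 100 ng of RNA carried through the Two-Cycle labelling kit, per the labels. The labels give 3 replicates for each of the 4 groups, and every array was assigned to its group from its label alone.

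The deposited value is a linear ratio, made from GCRMA signals per the submitters' processing notes, which give no version. The scaling is not stated in the labels and was read from the values: each probe set is divided by its own median over the 12 arrays. Of the 15617 rows, 12064 have a median of 1 within a tolerance of 1e-06, 3553 a median below 1 and 0 a median above 1, the form that a lower limit on the divisor would leave. Levels of different probe sets therefore cannot be compared, and no signal above background can be given. The lowest deposited ratio was 0.000773, so log2 values were taken without a pseudocount.

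The 115 control probe sets were left out of the probe sets tested and used to describe the arrays and, for the hybridisation controls, to form a block in 1 alternative, which left 15502 probe sets tested. A filter on low signal had been planned for values on an absolute scale and was not used, because the ratios are centred per probe set. The platform annotation gave 1 gene symbol for 10795 probe sets, several for 135 and none for 4572. Symbols were brought up to date through Entrez identifiers (10718 matched, 84 not matched, 1 symbol changed) with the gene table of the GRCz12tu assembly, which was used for names and gene positions only.

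Group means were fitted to all 12 arrays in 1 linear model with limma 3.58.1 (lmFit and eBayes) in R 4.3.3, with 8 residual degrees of freedom and a prior worth 2.08 more. The contrasts were TCDD minus vehicle at 2 dpa and at 3 dpa, 3 dpa minus 2 dpa within vehicle and within TCDD, and the difference of the TCDD effect between the days. A probe set was called at a Benjamini-Hochberg adjusted p under 0.05 over the 15502 probe sets. Tests are two-sided, and intervals are 95% intervals of the fit. With 3 arrays against 3, an exact permutation test cannot give a p below 0.1, so single genes rest on limma. The number of arrays limits the precision. These groups, contrasts, thresholds, lists and the rule for naming genes were chosen before the data were examined. The mean TCDD effect over both days was added after the comparisons between days had called no probe set. An unmoderated per-probe-set test was run beside limma, on the arrays of the compared groups only and so with fewer degrees of freedom. It differs from the limma fit in the arrays used as well as in moderation.

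A total of 31 gene lists was fixed for this tissue and exposure: AHR response genes and AHR pathway components; Wnt, FGF, BMP and TGF-beta, Hedgehog, retinoic acid and Notch signalling; blastema, epidermal, fin fold, cartilage and bone, and extracellular matrix genes; DNA replication and S phase, and mitosis; oxidative stress and NRF2, heat shock and unfolded protein, p53 and apoptosis, and inflammation genes; markers of neutrophils and macrophages, red blood cells, muscle, neural and eye tissue, pigment cells, liver, gut and yolk, endothelium and notochord; ribosomal proteins, oxidative phosphorylation, cholesterol synthesis and glycolysis. Each list had at least 5 measured members and was tested with camera in limma at its preset inter-gene correlation of 0.01, with p adjusted over the 31 lists of a comparison. The same lists were tested with a correlation estimated from the arrays and with fry, which asks whether a list's genes move one way on balance without comparing them with other genes. A gene with several probe sets was represented by the one with the highest mean deposited ratio, a choice made on relative values. As ratios are scaled to each probe set's own median, this rule favours probe sets that read high on some arrays. The choice is therefore not independent of the values tested. A list score for an array is the median log2 ratio of the list's genes on it. Scores of the 6 TCDD and 6 vehicle arrays were compared by an exact permutation test over 924 arrangements, chosen after the data were seen.

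Genes were chosen for naming by a fixed rule, and the text describes most of them. For TCDD on each day these were up to 10 per direction with the largest change among called probe sets whose 3 TCDD arrays all lay on one side of the 3 vehicle arrays, with 1 symbol that is not a clone name. For comparisons between days the limit was 5 per direction. cyp1a and rspo1 were always given, with called members of the AHR response and Wnt lists and up to 4 called members of each other list. Where fewer than 5 passed, the 5 of lowest p were given as not past the threshold. Chosen by the rule but not described in the results, a selection made after the values were seen, were jac1, ptpn6 and c6.2 for TCDD at 2 dpa, sox3, pik3r1, c6.2 and asip2b at 3 dpa, and jac1, spon2b, uchl1, sox3, gclm, atp5mc3a, tnni2b.1, sod2, grna, p4ha1b, rrm1, col1a2, jam2a and cfd for the mean, with most genes of lowest p between days. Also chosen for the mean, and named in the results only as list members, were rpl22, mcm2, mcm3 and atp5mf. Of these calls for the mean, those of jac1, sox3 and jam2a were kept whichever array was left out, and each of the others for 0 (rpl22) to 10 of the 12 arrays. Other chosen genes, such as daxx, cygb1 and klf2a, are described for some of their comparisons only. Named outside this rule, after their values were seen, were nqo1 and ptgs2a of the AHR response list, the sox9b values on single days, and genes given as examples of what a list holds.

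The pipeline was tested on simulated data with the 3 against 3 design. At 2 dpa, of 50 simulated probe sets per size, 31 were called at a 2-fold change (62%), 46 at 4-fold (92%), and 50 at 8-fold and at 16-fold. None of the 177 simulated calls fell on an unchanged probe set. The simulated noise was normal and drawn independently for each probe set. It held no correlation between genes and no grouping of arrays off the labels, so these shares may be too favourable for the real arrays.

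The alternatives tried were quantile normalization, centring each array on its median, eBayes with trend and robust settings, array weights, the replicate number as a block, leaving out multi-hit probe sets (917), 1 probe set per named gene, a pseudocount of 16, stricter thresholds, a fit of the compared groups alone, Spearman's coefficient, every other probe set of a named gene, the mean of a gene's probe sets, and each array left out in turn. Added after the data were seen were a pseudocount of 0.1, leaving out probe sets with a median below 1, the level of the 18 hybridisation control probe sets as a block (arrays with a mean log2 ratio above 0.1 against the others), leaving out 2 arrays that stand apart, the lists without an ambiguous mpx probe set, and the alternatives of the lists between days in TCDD fins. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.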

Results

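Gene expression was measured in caudal fin tissue that zebrafish larvae had regrown after amputation, with or without a 1 h exposure to TCDD, a dioxin that binds and activates the aryl hydrocarbon receptor (AHR). The 12 arrays formed 4 groups of 3: vehicle at 2 days post amputation (dpa), TCDD at 2 dpa, vehicle at 3 dpa and TCDD at 3 dpa. Each array held RNA from a pool of 150 fins per the labels, so the p-values measure variation between pools and not between larvae. Values are ratios to each probe set's median over the 12 arrays, on a log2 scale unless a fold or a ratio is named. Effects are differences of group means with the standard error (SE) of the limma fit, and 15502 probe sets were tested. The number of arrays limits the precision of every value.

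The comparison of TCDD with vehicle at 2 dpa asks which transcripts the exposure altered in the early regenerate. Among called genes with a symbol the largest increase was in cyp1a, which encodes a cytochrome P450 enzyme induced through the AHR. It was 8.70 higher with TCDD (SE 1.09, n = 3 against 3, adjusted p = 0.0165), a fold of 417 with a 95% interval from 77.2 to 2253. Over both days the 6 vehicle arrays read ratios from 0.000773 to 0.0241 for cyp1a and the 6 TCDD arrays from 1.98 to 4.30, so the fold rests on vehicle readings close to 0. A related AHR-induced enzyme gene, cyp1c1, rose by 6.06 (SE 0.82, adjusted p = 0.0238). The secreted enhancer of Wnt signalling rspo1 rose by 2.95 (SE 0.36, adjusted p = 0.0129), a fold of 7.75 with an interval from 4.47 to 13.4. The Wnt receptor gene fzd7a rose by 1.64 (SE 0.13, adjusted p = 0.00128). The largest decreases of such genes were in mb, which encodes the oxygen-binding protein myoglobin (−3.66, SE 0.49, adjusted p = 0.0215), and in kera, which encodes the matrix proteoglycan keratocan (−2.78, SE 0.21, adjusted p = 0.00128).

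In the GRCz12tu assembly cyp1a (Entrez 140634) lies on chromosome 18 from 1069707 to 1080591, and rspo1 (Entrez 436625) on chromosome 16 from 36997454 to 37041750. The gene fzd7a (Entrez 30369) lies on chromosome 9 from 13498611 to 13501345, and kera (Entrez 567017) on chromosome 4 from 16924197 to 16932100.

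At 2 dpa the limma fit called 25 probe sets, 14 higher and 11 lower with TCDD. There were 1583 with an unadjusted p under 0.05, where 775.1 would come by chance. The unmoderated per-probe-set test called 0. In 3107 probe sets (20%) the 3 TCDD arrays all lay on one side of the 3 vehicle arrays, against 10% by chance. Also higher were cyb5a, the electron carrier cytochrome b5 (2.97), ptgdsb.2, a prostaglandin D synthase (2.87), gchfr, the regulator of GTP cyclohydrolase (1.79), and sult6b1, a sulfotransferase (1.17). Also lower were the oxygen-binding cytoglobin gene cygb1 (−2.17) and the small heat shock protein gene hspb1 (−1.91). A probe set annotated to the neutrophil peroxidase gene mpx rose by 3.23, while 3 other mpx probe sets read −0.49, −0.04 and −0.01. All 4 share the cluster number of the cyp1a probe set in their names, so the name does not set the one that rose apart.

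The calls for kera, fzd7a, cyb5a, gchfr and this mpx probe set at 2 dpa held whichever single array was left out, and several others did not. The adjusted p of cyp1a was 0.0789, 0.0817 and 0.0816 without TCDD 2 dpa replicate 1, 2 and 3, and ranged from 0.000153 to 0.0827 over its alternatives. The call of rspo1 was lost without vehicle 2 dpa replicate 1 (0.0736) or 2 (0.0616), in a range from 0.00362 to 0.0736. The call of mb was lost without any 1 of the 6 arrays of this day (0.0598 to 0.101, in a range from 0.00445). The call of cyp1c1 was lost without any of them (0.0829 to 0.111, in a range from 0.00218) and without vehicle 3 dpa replicate 2 (0.0556). A further cyp1c1 probe set read 0.09 (adjusted p = 0.839). The call of hspb1 was lost without vehicle 2 dpa replicate 1 (0.0512) or 3 (0.0627), and that of ptgdsb.2 without the same replicates (0.0644 and 0.052). Of the 12 arrays, leaving out 1 ended the call of sult6b1 for 7 and of cygb1 for 9. The count of called probe sets was 8 without vehicle 2 dpa replicate 1, 13 and 9 without replicates 2 and 3, and 11, 12 and 11 without TCDD 2 dpa replicates 1, 2 and 3. It was 16 without vehicle 3 dpa replicate 2, 49 without vehicle 3 dpa replicate 3 and 39 without TCDD 3 dpa replicate 2, from 25 with every array.

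**Figure D1:**
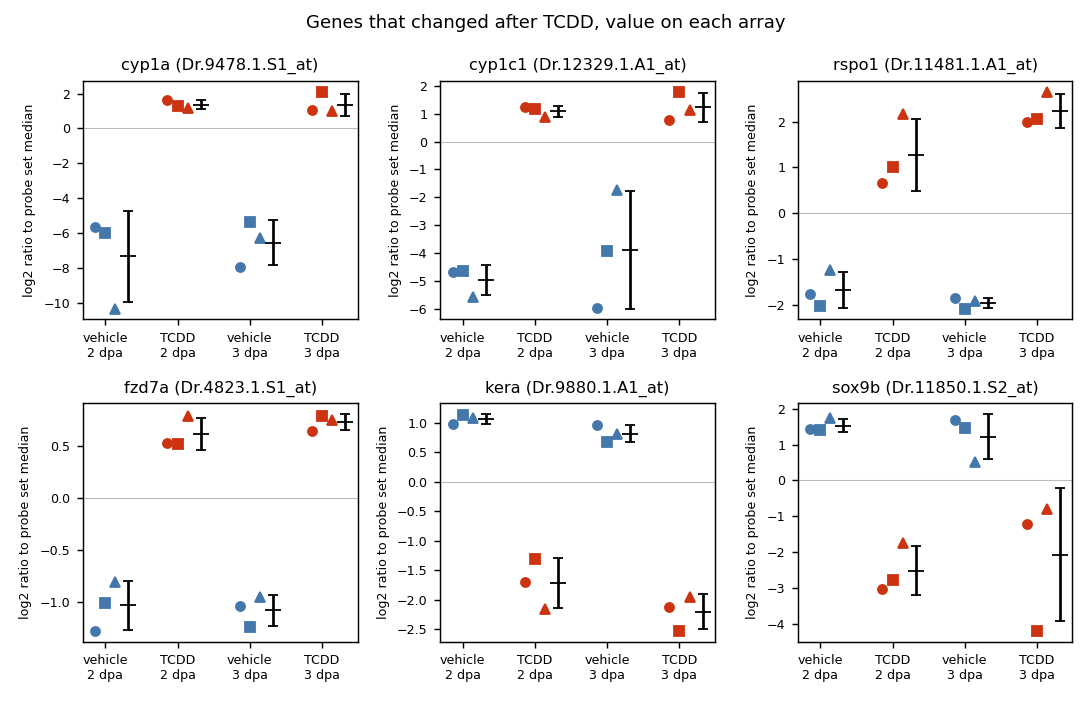
Level of 6 genes (cyp1a, cyp1c1, rspo1, fzd7a, kera and sox9b) on each array, as the log2 ratio to the probe set's median (vertical axis), for vehicle (blue) and TCDD (red) at 2 and 3 dpa, with circles, squares and triangles for replicates 1, 2 and 3 and bars for the mean ± SD of the 3 arrays of a group. The TCDD arrays lie above every vehicle array for cyp1a, rspo1 and fzd7a and below every vehicle array for kera.

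As a group, 7 measured AHR response genes had a median of 1.02 at 2 dpa (camera adjusted p = 5.66e-07, adjusted p = 0.0188 with an estimated correlation). Of them cyp1a, cyp1c1 and sult6b1 were called higher and 4 were not called, and adjusted over the list alone 4 were higher and 1 lower. The genes not called included, named outside the naming rule, nqo1, a quinone reductase gene (−0.36), and ptgs2a, a prostaglandin synthase gene (0.72). The DNA replication and S phase genes, among them the helicase subunit genes mcm2 and mcm3, had a median of −0.89, with 42 of 42 members lower (adjusted p = 1.06e-12, adjusted p = 0.56 with an estimated correlation). None of them was called alone at 2 dpa, and adjusted over the list alone 2 were lower. The mitosis genes, among them the cyclin gene ccnb1 and the kinase gene plk1, had a median of −0.74 with 32 of 35 lower (adjusted p = 9.32e-08, adjusted p = 0.56 with an estimated correlation), 0 called and 6 lower adjusted over the list alone. Without vehicle 2 dpa replicate 3 the medians of these lists were −0.39 (adjusted p = 2.59e-06, in a range from 4.2e-19 to 0.56) and −0.24 (adjusted p = 0.000768, in a range from 1.66e-12 to 0.56). The extracellular matrix genes, which encode collagens, their cross-linking enzymes and proteases, had a median of −0.28 with 24 of 30 lower (adjusted p = 0.00171, adjusted p = 0.123 with an estimated correlation, fry adjusted p = 0.00241). None was called, and adjusted over the list alone 2 were lower. In every TCDD array the ratio of the 5' to the 3' GAPDH control probe sets was higher (0.169 to 0.486) than in every vehicle array (−0.102 to 0.0816), and the scores of these 4 lists also separated all TCDD from all vehicle arrays.

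Other lists were also past the threshold at 2 dpa. The ribosomal protein genes, such as rpl22, had a median of −0.25 with 59 of 60 lower (adjusted p = 2.11e-09, adjusted p = 0.56 with an estimated correlation). The oxidative phosphorylation genes, such as the ATP synthase subunit genes atp5mc1 and atp5mf, had a median of −0.26 with 48 of 55 lower (adjusted p = 0.000361, adjusted p = 0.668 with an estimated correlation), and −0.16 without TCDD 2 dpa replicate 3 (adjusted p = 0.0245, in a range from 1.28e-06 to 0.668). The epidermal genes, such as keratins, had a median of 0.19 with 29 of 41 higher (adjusted p = 0.0353, adjusted p = 0.56 with an estimated correlation). All 7 measured fin fold genes, such as and1 and and2 of the actinotrichia fibrils, were lower, with a median of −0.42 (adjusted p = 0.0391, adjusted p = 0.56 with an estimated correlation). The p53 target and apoptosis genes had a median of 0.20 (adjusted p = 0.0353, adjusted p = 0.56 with an estimated correlation). The neural and eye markers had a median of 0.07 (adjusted p = 0.0235, adjusted p = 0.602 with an estimated correlation), and the AHR pathway components a median of 0.14 (adjusted p = 0.0353, adjusted p = 0.312 with an estimated correlation). No member of these 7 lists was called alone, and adjusted over the list alone 1 epidermal gene was higher, 2 p53 genes were higher and 2 lower, and 0 genes of the other 5 differed. Leaving out 1 array ended the call of the epidermal list for 4 of the 12 arrays, of the fin fold list for 6, of the p53 list for 3, of the neural list for 2 and of the AHR components for 3. In these fits the median ranged from 0.06 to 0.38 for the AHR components, from 0.03 to 0.31 for the epidermal list and from 0.06 to 0.30 for the p53 list. For the ribosomal protein list, whose call was kept for all 12, it ranged from −0.33 to −0.16. Without TCDD 2 dpa replicate 3 the epidermal median was 0.03 (adjusted p = 0.388, in a range from 0.00192 to 0.56) and the p53 median 0.06 (adjusted p = 0.163, in a range from 0.0226 to 0.56). Without TCDD 2 dpa replicate 1 the neural median was −0.00 (adjusted p = 0.2, in a range from 0.00224 to 0.602).

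The comparison of TCDD with vehicle at 3 dpa asks the same of the later regenerate. The AHR-induced genes cyp1a and cyp1c1 rose by 7.92 (SE 1.09, n = 3 against 3, adjusted p = 0.0163) and 5.11 (SE 0.82, adjusted p = 0.0285), and tiparp, the TCDD-inducible poly-ADP-ribose polymerase gene, by 1.32 (SE 0.19, adjusted p = 0.0199). The Wnt enhancer gene rspo1 rose by 4.19 (SE 0.36, adjusted p = 0.00104), a fold of 18.2 with an interval from 10.5 to 31.6. The receptor gene fzd7a rose by 1.80 (SE 0.13, adjusted p = 0.000479). The largest decreases were in mb (−3.45, SE 0.49, adjusted p = 0.0185), in klf2a, a transcription factor that responds to blood flow (−3.27, SE 0.55, adjusted p = 0.0331), in kera (−3.02, SE 0.21, adjusted p = 0.000479) and in postnb, which encodes the matrix protein periostin (−2.64, SE 0.43, adjusted p = 0.0299). Also lower were sulf2b, a sulfatase of heparan sulfate (−2.52), dut, the dUTPase of nucleotide synthesis (−2.00), orc3 of the origin recognition complex (−1.51), the mesenchymal homeobox gene prrx1b (−1.39) and the retinol carrier gene rbp4 (−1.37). Also higher were ptgdsb.2 (3.01), cyb5a (2.84), the chloride channel gene ano1a (2.27), the homeobox gene dlx4b (1.82) and sult6b1 (1.37).

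At 3 dpa the limma fit called 89 probe sets, 44 higher and 45 lower, and 2434 had an unadjusted p under 0.05. The unmoderated per-probe-set test called 0. Groups did not overlap in 2525 probe sets (16.3%, against 10% by chance). Hybridisation control probe sets read higher on the 3 vehicle 3 dpa arrays (0.264, 0.260 and 0.292) and TCDD 3 dpa replicate 2 (0.344) than on the other 8 arrays (−0.143 to −0.0125). With this level as a block, which at 3 dpa sets replicate 2 of the TCDD group alone against the 3 vehicle arrays, 217 probe sets were called, of which 34 were among the 89. In that fit cyp1a (8.65, adjusted p = 0.0394, in a range from 0.000191 to 0.0734), rspo1 (4.01, adjusted p = 0.0111, in a range from 0.000161), fzd7a (1.86, adjusted p = 0.00414, in a range from 0.000318 to 0.00518) and kera were still called. Calls that ended in it were those of cyp1c1 (0.0604), mb (0.0749), klf2a (0.121), postnb (0.08), sulf2b (0.107), dut (0.0861), prrx1b (0.198) and ano1a (0.143).

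Leaving out single arrays also ended calls at 3 dpa. For cyp1a these were vehicle 3 dpa replicate 1 (0.0734) and TCDD 3 dpa replicate 3 (0.0562), for rbp4 vehicle 3 dpa replicates 1 (0.0799) and 2 (0.0729), and for tiparp vehicle 3 dpa replicates 1 (0.0757) and 2 (0.0729) and TCDD 3 dpa replicate 1 (0.0558). The call of mb was lost for 4 of the 12 arrays, of orc3 and dlx4b for 5, of cyp1c1, ano1a, klf2a and sulf2b for 7, of dut and postnb for 8 and of prrx1b for 10. The calls of rspo1, fzd7a, kera, cyb5a, gchfr, ptgdsb.2 and sult6b1 held for all 12. The count of called probe sets was 42 and 49 without vehicle 2 dpa replicates 1 and 2, 28 and 32 without vehicle 3 dpa replicates 1 and 2, 59 without TCDD 2 dpa replicate 2 and 29 without TCDD 3 dpa replicate 3. It was 294 without TCDD 2 dpa replicate 3 and 391 without TCDD 3 dpa replicate 2, from 89 with every array.

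The AHR response genes had a median of 1.32 at 3 dpa (camera adjusted p = 0.000141, adjusted p = 0.0626 with an estimated correlation, fry adjusted p = 0.000314), with tiparp called beside cyp1a, cyp1c1 and sult6b1. Adjusted over the list alone 5 were higher and 1, nqo1, was lower. The DNA replication and S phase genes had a median of −0.90 with 41 of 42 lower (adjusted p = 4.15e-12, adjusted p = 0.631 with an estimated correlation). Of them dut and orc3 were called lower, and 12 were lower adjusted over the list alone. The mitosis genes had a median of −0.75 with 32 of 35 lower (adjusted p = 0.00015, adjusted p = 0.675 with an estimated correlation), 0 called, and 1 higher adjusted over the list alone. With the mean of all probe sets of a gene the mitosis median was −0.45 (adjusted p = 0.000132, in a range from 7.43e-09 to 0.675). The extracellular matrix genes had a median of −0.20 with 22 of 30 lower (adjusted p = 0.00609, adjusted p = 0.217 with an estimated correlation, fry adjusted p = 0.00496). The metalloproteinase gene mmp14b was called lower (−0.61), a call kept for 2 of the 12 arrays left out and ended by the hybridisation block (0.117, in a range from 0.0141 to 0.144). Adjusted over the list alone 11 were lower and 1 higher. Without vehicle 3 dpa replicate 3 the matrix list had a median of −0.31 and an adjusted p of 0.0505, in a range from 0.00277 to 0.217.

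The epidermal genes had a median of 0.33 with 33 of 41 higher (adjusted p = 0.000269, adjusted p = 0.631 with an estimated correlation) and dlx4b called higher, and adjusted over the list alone 2 were higher and 1 lower. The 7 fin fold genes were again all lower (−0.30, adjusted p = 0.0292, adjusted p = 0.652 with an estimated correlation). The NRF2 target genes, which respond to oxidative stress, had a median of 0.20 (adjusted p = 0.0381, adjusted p = 0.631 with an estimated correlation), with the glutathione transferase gene gsto2 called higher (0.70), and adjusted over the list alone 5 were higher and 1 lower. The gsto2 call was lost for 3 of the 12 arrays left out and with the hybridisation level as a block (0.0757, in a range from 0.00473). The skeletal muscle markers had a median of 0.15 (adjusted p = 0.0301, adjusted p = 0.729 with an estimated correlation). With the hybridisation level as a block these lists were not past the threshold: the epidermal list had a median of 0.17 (0.125, in a range from 2.67e-05 to 0.631), the fin fold list −0.19 (0.82, in a range from 0.00606), the NRF2 list 0.11 (0.38, in a range from 0.0134 to 0.631) and the muscle list 0.07 (0.38, in a range from 0.000121 to 0.982). Without TCDD 3 dpa replicate 3 the muscle median was 0.00 (0.982) and the fin fold median −0.21 (0.218). Leaving out 1 array kept the call of the fin fold list for 10 of the 12 arrays, of the NRF2 list for 7 and of the muscle list for 9. The median ranged from 0.11 to 0.32 for the NRF2 list and from 0.00 to 0.42 for the muscle list. The ribosomal protein genes had a median of −0.16 with 59 of 60 lower (adjusted p = 0.000334, adjusted p = 0.729 with an estimated correlation), and the oxidative phosphorylation genes −0.20 with 46 of 55 lower (adjusted p = 0.00161, adjusted p = 0.729 with an estimated correlation). Adjusted over the list alone 0 genes of the fin fold, muscle, ribosomal and oxidative phosphorylation lists differed. Without vehicle 3 dpa replicate 1 they were −0.04 (0.238, in a range from 3.83e-10 to 0.729) and −0.08 (0.143, in a range from 1.3e-11 to 0.729). Without TCDD 3 dpa replicate 2 they were −0.11 (0.0806) and −0.12 (0.2), and without vehicle 3 dpa replicate 2 the oxidative phosphorylation genes were at −0.10 (0.121). Without vehicle 3 dpa replicate 3 they were −0.29 and −0.40, and with the hybridisation level as a block −0.28 and −0.34.

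Effects of TCDD on both days were set side by side for each probe set. All 25 probe sets called at 2 dpa had the same sign at 3 dpa, among them cyp1a, rspo1, fzd7a, kera and mb. Of these, 13 were called higher on both days and 5 lower on both days, where 0.0397 and 0.0319 would be shared if the calls were independent. Calls on both days use 1 estimate of the spread per probe set, so they are not independent. The expected numbers may therefore be too low even without a shared effect. Over all probe sets the effects had a Pearson r of 0.793 and a Spearman rho of 0.640, and 10769 (69.5%) had the same sign. This correlation is across genes, which are not independent replicates. It was 0.498 with the hybridisation level as a block.

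**Figure D2:**
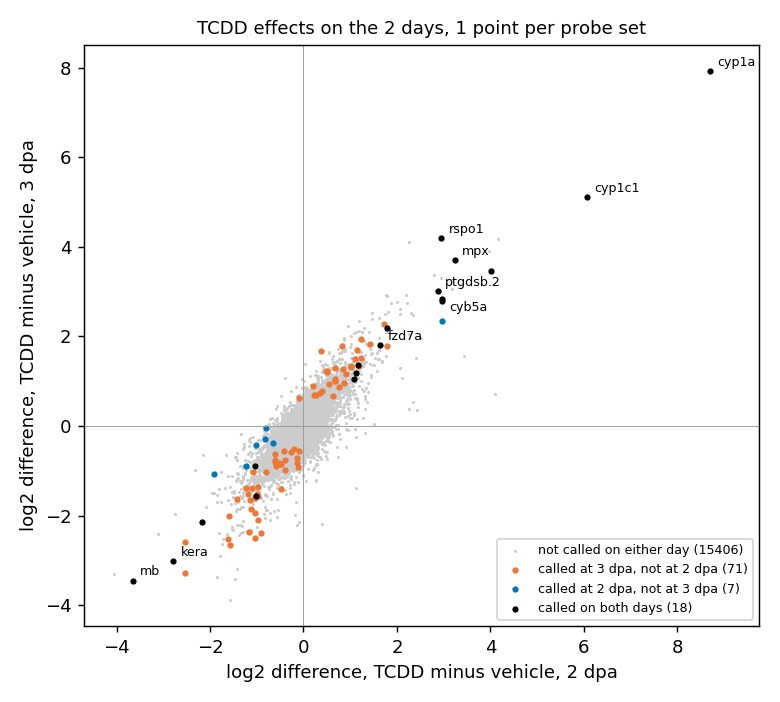
TCDD effect (log2 difference of group means, TCDD minus vehicle) at 2 dpa (horizontal axis) and 3 dpa (vertical axis), 1 point per probe set, coloured by the day on which it was called. The 18 probe sets called on both days lie in the corners where both effects have the same sign, 71 were called at 3 dpa only and 7 at 2 dpa only.

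The mean TCDD effect over both days, 6 arrays against 6, was examined after the comparisons between days had given no call, and describes what the exposure altered on average. It held the AHR-induced cyp1a (8.31, SE 0.77, adjusted p = 0.000909), the Wnt enhancer rspo1 (3.57, SE 0.25, adjusted p = 0.000124) and the receptor fzd7a (1.72, adjusted p = 2.59e-05). The called gene with the largest decrease was sox9b, a transcription factor of cartilage formation (−3.68, SE 0.54, adjusted p = 0.00786), a 12.8-fold decrease with an interval from 5.60 to 29.3. It lies on chromosome 3 from 67516105 to 67521447 (Entrez 60642). It was not called on either day alone (−4.05, adjusted p = 0.0908 at 2 dpa, and −3.30, adjusted p = 0.0891 at 3 dpa), and its other probe set read 0.01 (adjusted p = 0.951). The blastema homeobox genes msx1a (−0.83, SE 0.13, adjusted p = 0.0117) and prrx1b (−1.31, SE 0.18, adjusted p = 0.00502) fell, as did the periostin gene postnb (−2.11, SE 0.30, adjusted p = 0.00767), the retinol carrier rbp4 (−1.24), the TGF-beta-induced matrix gene tgfbi (−1.17), the dUTPase gene dut (−1.80) and the heat shock protein gene hspb1 (−1.49). The Dlx homeobox gene dlx4b (1.63), the autophagy receptor gene sqstm1 (0.68), ano1a (2.00) and tiparp (1.17) rose. Each of these calls held without any single array.

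The limma fit called 775 probe sets in this contrast, 279 higher and 496 lower, and 3333 had an unadjusted p under 0.05. The count was 1471 without TCDD 3 dpa replicate 2, 296, 342 and 409 without vehicle 2 dpa replicates 1, 2 and 3, 298 and 434 without vehicle 3 dpa replicates 1 and 2, 440 without TCDD 2 dpa replicate 3, and 423 and 403 without TCDD 3 dpa replicates 1 and 3. With the hybridisation level as a block it was 387, of which 203 were among the 775. The block ended the calls of the receptor gene fzd10 (−1.15, 0.0741), the cyclin gene ccnb1 (−1.23, 0.0677), the growth factor carrier gene igfbp2a (−2.19, 0.057), the pro-apoptotic gene bada (1.02, 0.0621) and the ATP synthase gene atp5mc1 (−0.66, 0.0549).

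Of the lists past the threshold in the mean effect, only the AHR response list was also past it with an estimated correlation. The AHR response list had a median of 1.17 (camera adjusted p = 2.49e-05, adjusted p = 0.0469 with an estimated correlation), with 4 of 7 called higher, and 5 higher and 1 lower adjusted over the list alone. The S phase list had a median of −0.88 with 41 of 42 lower (adjusted p = 7.1e-14, adjusted p = 0.525 with an estimated correlation), 10 called lower and 33 lower adjusted over the list alone. The mitosis list had a median of −0.67 with 31 of 35 lower (adjusted p = 8.73e-07, adjusted p = 0.59 with an estimated correlation). In it 7 genes were called lower, such as the kinase gene plk1 (−1.32) and the checkpoint gene mad2l1 (−1.30), and the kinesin gene kif20a higher (1.60). These 3 calls were kept for 10, 5 and 7 of the 12 arrays left out singly. The hybridisation level as a block ended them (0.0922, in a range from 0.00417; 0.103, from 0.0143; and 0.105, from 0.00782), and another kif20a probe set read 0.00 (adjusted p = 0.994). Adjusted over the list alone 20 were lower and 2 higher. The extracellular matrix list had a median of −0.21 with 23 of 30 lower (adjusted p = 0.00177, adjusted p = 0.132 with an estimated correlation, fry adjusted p = 0.000196). In it 7 genes were called lower, such as the collagen cross-linking lysyl oxidase genes loxa (−2.12) and loxl2b (−2.11), and 13 were lower and 3 higher adjusted over the list alone. The calls of loxa and loxl2b were kept for 6 and 5 of the 12 arrays left out, and the block ended them (0.11, in a range from 0.00376, and 0.119, in a range from 0.00298). In an exact permutation test of list scores, 6 TCDD against 6 vehicle arrays, these 4 lists had p = 0.00216, the smallest that 924 arrangements can give (adjusted 0.0168). No other list was past the threshold in this test. The arrangements did not keep to the days. Nearest to the threshold were the cartilage and bone (adjusted p = 0.0537), NRF2 (0.0559) and pigment cell (0.0575) lists. Among the other lists past the camera threshold, the adjusted p was 0.0671 for fin fold, 0.116 for ribosomal protein and 0.116 for p53 genes. It was 0.163 for epidermal, 0.335 for oxidative phosphorylation and 0.661 for muscle genes. Mean scores with TCDD and vehicle were 0.58 and −0.50 for the AHR list, −0.26 and 0.57 for S phase, −0.26 and 0.41 for mitosis, and −0.21 and 0.08 for the matrix. Vehicle arrays were uneven: S phase scores were 0.08, 0.06 and 1.41 at 2 dpa and 0.86, 0.05 and 0.95 at 3 dpa, against −0.44 to −0.07 with TCDD.

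**Figure D3:**
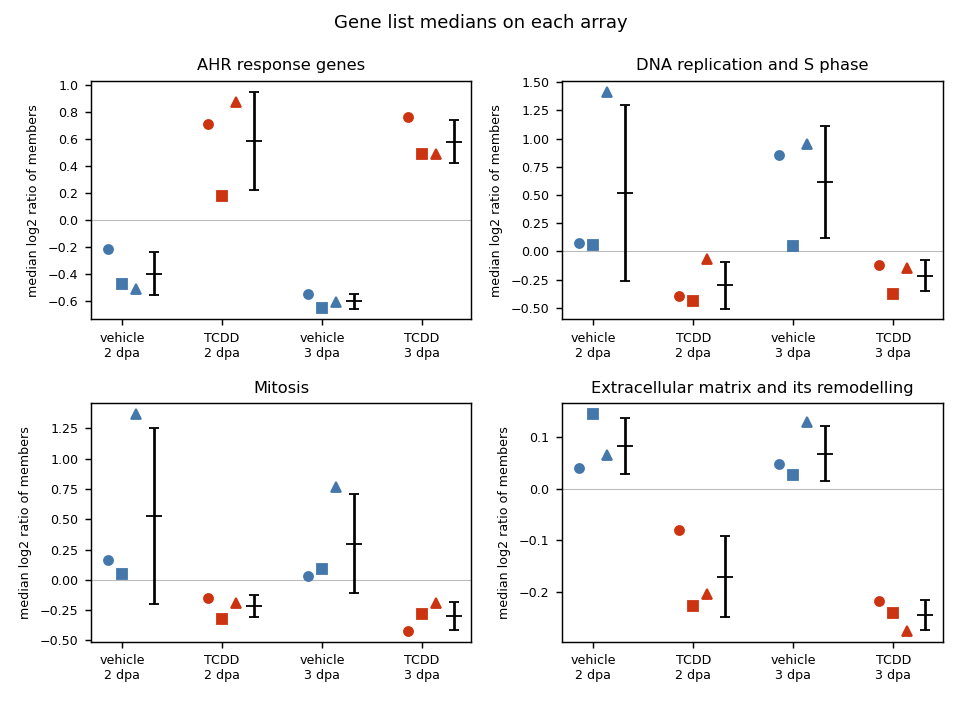
Median log2 ratio of the genes of 4 lists (AHR response, DNA replication and S phase, mitosis, extracellular matrix) on each array (vertical axis), for vehicle (blue) and TCDD (red) at 2 and 3 dpa, 1 point per array. S phase scores of the 6 TCDD arrays lie from −0.44 to −0.07, below all vehicle arrays, whose highest is 1.41.

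Also past the threshold in the mean effect were the ribosomal protein list (−0.21, 59 of 60 lower, adjusted p = 1.34e-07, adjusted p = 0.59 with an estimated correlation) and the oxidative phosphorylation list (−0.23, 47 of 55 lower, adjusted p = 0.000187, adjusted p = 0.637 with an estimated correlation). The epidermal list had a median of 0.30 with 31 of 41 higher (adjusted p = 0.000989, adjusted p = 0.525 with an estimated correlation), with dlx3b and dlx4b called higher and dlx4a and krt91 lower (4 higher and 2 lower adjusted over the list alone). With single arrays left out the call of dlx4b was kept for all 12, of dlx3b and dlx4a for 3 and of krt91 for 6. The block ended these last 3 (0.162, in a range from 0.0177, 0.146, from 0.012, and 0.102, from 0.0126). The fin fold list (−0.34, adjusted p = 0.019, adjusted p = 0.547 with an estimated correlation), the p53 list (0.23, adjusted p = 0.0459, adjusted p = 0.59 with an estimated correlation) and the muscle list (0.15, adjusted p = 0.0242, adjusted p = 0.7 with an estimated correlation) were not past it with the hybridisation level as a block, at −0.24 (0.224, in a range from 0.0045 to 0.547), 0.01 (0.679, in a range from 0.00443) and 0.07 (0.21, in a range from 0.000469 to 0.7). Leaving out TCDD 3 dpa replicate 3 also ended these 3 calls, at −0.30 (0.0554), 0.06 (0.102) and 0.05 (0.392). In the p53 list bbc3 (1.13) and phlda3 (0.69) were called higher beside bada and gadd45ab lower (−1.02), kept for 2, 3, 12 and 12 of the 12 arrays left out in the order bbc3, phlda3, bada and gadd45ab. The block ended all but gadd45ab (0.111, in a range from 0.0211, for bbc3 and 0.164, from 0.0123, for phlda3). The p53 list call was lost for 5 more arrays: vehicle 2 dpa replicates 2 (0.0656) and 3 (0.0714), vehicle 3 dpa replicate 3 (0.101), TCDD 2 dpa replicate 3 (0.0825) and TCDD 3 dpa replicate 1 (0.0901). The muscle call was also lost without vehicle 3 dpa replicate 3 (0.0625) or TCDD 2 dpa replicate 1 (0.115). Although 34 of 38 muscle markers were higher, none was called higher and 1 was called lower, with the same counts adjusted over the list alone. Over the 12 arrays left out singly the p53 median ranged from 0.06 to 0.40, the muscle median from 0.05 to 0.26 and the epidermal median from 0.19 to 0.33.

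Wnt pathway genes were called in both directions, but only some calls held. In the mean effect rspo1, fzd7a and the Wnt inhibitor gene dkk1b (1.28) were called higher, and the feedback gene axin2 (−0.63) and the receptor genes fzd10 and fzd8a (−0.88) lower. The calls of rspo1, fzd7a and fzd10 were kept whichever of the 12 arrays was left out, of dkk1b and axin2 for 2 and of fzd8a for 1. With the hybridisation level as a block those of dkk1b, axin2, fzd8a and fzd10 ended (0.188, in a range from 0.00938, 0.199, from 0.0249, 0.19, from 0.0192, and 0.0741, from 0.00462), so in that fit none of the 3 lower genes was called. Another fzd8a probe set read −0.31 (adjusted p = 0.52). The median of the 37 measured genes was −0.01 and their mean 0.10, with a camera adjusted p of 0.83 for a higher list and a fry adjusted p for change in either direction of 8.15e-08. Most of the 31 lists were past the threshold in that fry test. The neutrophil and macrophage list was lowest in it (fry adjusted p = 9.21e-10), so the value does not set the Wnt list apart. The 25 cartilage and bone genes had a median of −0.02 and a mean of −0.42 (camera adjusted p = 0.104). In this list 6 genes were called lower, among them sox9b, postnb, the collagen gene col11a1a (−1.54) and the chondromodulin gene cnmd (−1.33). The last 2 were kept for 2 of the 12 arrays left out each, and the block ended them (0.159, in a range from 0.0128, and 0.196, in a range from 0.0208). The 33 blastema genes had a median of −0.01 and a mean of 0.05 (adjusted p = 0.808), with evx1 called higher (0.87, kept for 4 of the 12 arrays left out) beside msx1a and prrx1b lower. The 30 BMP and TGF-beta genes had a median of −0.04 (adjusted p = 0.808), with the antagonist gene fsta (1.58) and the ligand gene bmp2a (0.48) higher and tgfbi and id2b (−1.24) lower. Of 12 single arrays left out, the call was kept for 11 for fsta, 12 for tgfbi and 2 each for bmp2a and id2b. The 16 retinoic acid genes had a median of −0.12 (camera adjusted p = 0.171) with rbp4 lower, and fry, which asks whether they move one way on balance, gave an adjusted p of 0.008 (0.0177 at 2 dpa and 0.155, not past the threshold, at 3 dpa). The 15 pigment cell genes had a median of −0.16 (adjusted p = 0.0784), with dct (−1.45), gch2 (−1.77) and mitfa (−0.87) of melanin and pteridine pigment formation lower, kept for 6, 5 and 10 of the 12 arrays left out. The block ended the calls of evx1 (0.0872, in a range from 0.013), fsta (0.0704, from 0.00298), bmp2a (0.135, from 0.00951), id2b (0.184, from 0.0273), dct (0.0992, from 0.0107) and gch2 (0.143, from 0.00403). Other probe sets read 0.41 for fsta (adjusted p = 0.47), −0.33 for id2b (0.141) and −0.03 for gch2 (0.781). The 21 neutrophil and macrophage markers had a median of 0.06 (adjusted p = 0.323).

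The comparison of 3 dpa with 2 dpa asks what changed as regrowth went on. In vehicle fins the limma fit called 0 probe sets, 578 had an unadjusted p under 0.05 where 775.1 would come by chance, and the unmoderated per-probe-set test called 0. Groups did not overlap in 1720 (11.1%, against 10% by chance). The genes of lowest p, none past the threshold (adjusted p = 1), included cad of pyrimidine synthesis (0.70) and the chromatin regulator gene daxx (−0.65). In TCDD fins 0 were called, 621 had an unadjusted p under 0.05, groups did not overlap in 859 (5.54%, against 10% by chance), and the unmoderated test called 0. There rspo1 differed by 0.96 and cyp1a by 0.00, neither past the threshold (lowest adjusted p of all probe sets 0.983). The oxidative phosphorylation genes were lower at 3 dpa in vehicle (−0.22, 51 of 55 lower, adjusted p = 1.56e-05, adjusted p = 0.919 with an estimated correlation) and in TCDD fins (−0.20, 49 of 55 lower, adjusted p = 2.57e-05, adjusted p = 0.983 with an estimated correlation). In vehicle fins the ribosomal protein genes were lower (−0.11, 48 of 60 lower, adjusted p = 0.023, adjusted p = 0.919 with an estimated correlation) and the neural and eye markers higher (0.03, 28 of 41 higher, adjusted p = 0.046, adjusted p = 0.919 with an estimated correlation). Without vehicle 3 dpa replicate 3 these 3 vehicle medians were −0.01 (0.914, in a range from 4.73e-09 to 0.998), 0.01 (0.544, in a range from 1.79e-08 to 0.998) and −0.01 (0.544, in a range from 0.0144 to 0.998). With the hybridisation level as a block, where all 3 vehicle 3 dpa arrays share a level, they were 0.02, 0.07 and −0.08. In TCDD fins the muscle markers were higher (0.20, 31 of 38 higher, adjusted p = 0.0213) and the heat shock genes lower (−0.17, 20 of 32 lower, adjusted p = 0.025), each with an adjusted p = 0.983 with an estimated correlation. Without TCDD 3 dpa replicate 3 the muscle median was −0.017 (0.92, in a range from 2.28e-05 to 0.993) and the heat shock median −0.14 (0.513, in a range from 6.34e-06 to 0.993). The muscle call was also lost without TCDD 2 dpa replicates 2 (0.222) and 3 (0.318) and with quantile normalization (0.0624), and the heat shock call without these (0.191 and 0.0751) or TCDD 3 dpa replicate 2 (0.63). The heat shock median was −0.45 without TCDD 3 dpa replicate 1 and −0.27 without TCDD 2 dpa replicate 1, and the muscle median 0.33 without TCDD 3 dpa replicate 1 and 0.29 without TCDD 3 dpa replicate 2. The oxidative phosphorylation call was lost without TCDD 2 dpa replicate 1 (−0.09, 0.129, in a range from 6.64e-08 to 0.993) or TCDD 3 dpa replicate 2 (−0.10, 0.0855). With the hybridisation level as a block the values of the heat shock, muscle and oxidative phosphorylation lists are those without TCDD 3 dpa replicate 2.

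The difference of the TCDD effect between days asks whether the exposure acted otherwise on the later regenerate. The limma fit called 0 probe sets, 226 had an unadjusted p under 0.05, and no list was past the threshold (lowest camera adjusted p = 0.196). The effect on rspo1 was 1.24 larger at 3 dpa (SE 0.50, adjusted p = 1) and that on cyp1a 0.78 smaller (SE 1.55, adjusted p = 1), so the larger number of calls at 3 dpa does not show a larger effect. With both arrays left out that stood apart from their groups, chosen after the distances were seen, 364 probe sets were called between days in TCDD fins, among them rspo1 (1.49, adjusted p = 0.0442, in a range up to 1), and 60 in the difference of effects. Leaving out arrays for their distance lowers the spread within groups by its own construction. These arrays were TCDD 2 dpa replicate 3, which lay 0.279 from TCDD 3 dpa replicate 1 and 0.57 and 0.56 from its own group, and TCDD 3 dpa replicate 2, which lay 0.46 from TCDD 2 dpa replicate 2 and 0.65 and 0.72 from its own group. The array vehicle 3 dpa replicate 3 was not left out with them. It lay 0.521 from TCDD 3 dpa replicate 2 and 0.535 and 0.55 from its own group, and its array weight was 0.371, beside 0.392 and 0.28 for the other 2.

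**Figure D4:**
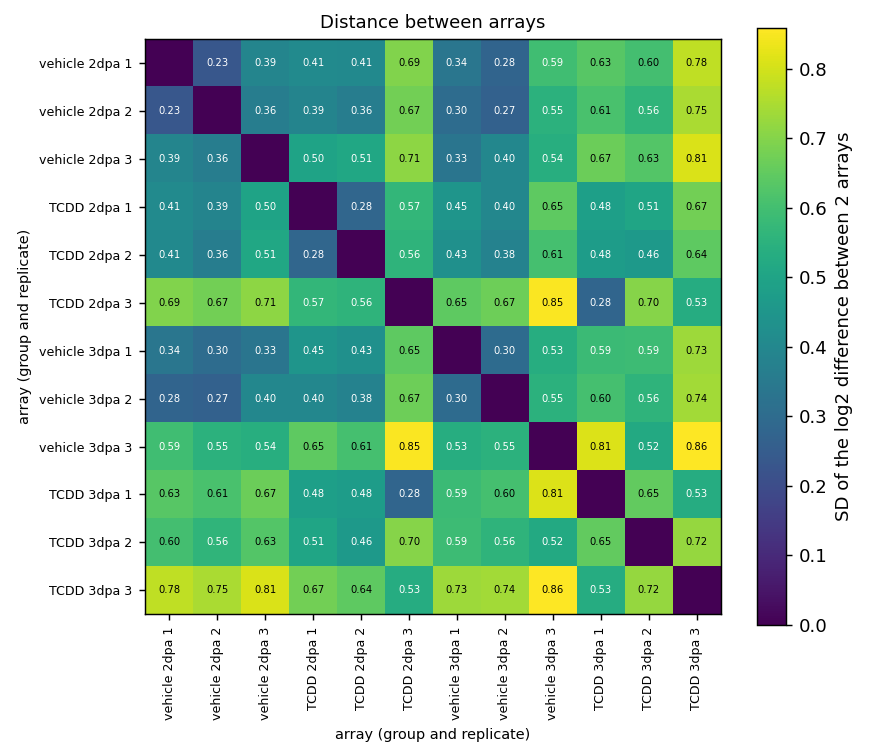
Distance between each pair of the 12 arrays, as the SD over probe sets of their log2 difference (colour scale), with arrays ordered by group and replicate on both axes. TCDD 2 dpa replicate 3 and TCDD 3 dpa replicate 1 are 0.279 apart, while TCDD 3 dpa replicate 2 is 0.65 and 0.72 from its own group.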

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

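The tests of the 3 patterns weighed here (arrays apart from their group, the mpx probe set, and the S phase genes) were all chosen after the patterns were seen.

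Control probe sets, which were not among those tested, read beyond every vehicle array on some TCDD arrays. The mean log2 ratio of the hybridisation controls was 0.344 on TCDD 3 dpa replicate 2, above the highest vehicle array (0.292), and this was the only TCDD array above it. The log2 ratio of the 5' to the 3' GAPDH control was 0.486 on TCDD 3 dpa replicate 3, above the highest vehicle array (0.0816), and all 6 TCDD arrays were above it. The ratio of the middle actin control was 3.36 on TCDD 3 dpa replicate 3, above the highest vehicle array (1.07), with 4 TCDD arrays above it. The ratio of the 3' actin control was 5.32 on the same array, above the highest vehicle array (1.39), with 2 TCDD arrays above it. Both actin controls are named after acta1, and the muscle list holds acta1a and acta1b. The muscle list score was also highest on this array (0.267, with 0.0231 next). Its actin readings therefore cannot be told apart from a higher level of muscle transcripts in that pool.

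The S phase genes were lower with TCDD, and the GAPDH ratio separated the same arrays. A hybridisation difference as the whole cause is argued against, since the median over both days was −1.003 with the hybridisation level as a block (adjusted p = 2.72e-13 by camera with its preset correlation), and so are different value distributions, since it was −0.859 after quantile normalization (adjusted p = 3.34e-15), though with an estimated correlation the list is not past the threshold (adjusted p = 0.525). A lower 3' bias of the TCDD samples and an effect of the exposure cannot be told apart, because the GAPDH ratio separates TCDD from vehicle on every array, by a gap of 0.0873, and either may account for part of the difference. Within an exposure the bias would need a negative relation of ratio and score: Pearson's r was 0.273 over 6 vehicle arrays (exact permutation p = 0.601, rho 0.543, p = 0.297) and 0.428 over 6 TCDD arrays (p = 0.471, rho 0.486, p = 0.356), with adjusted p of 0.601 for both r and 0.356 for both rho. Without the 2 farthest arrays r was 0.542 and 0.00356, so the positive sign does not exclude the bias.

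The mpx probe set that rose with TCDD may detect neutrophils or cyp1a transcript; 3 other mpx probe sets share the cluster number of cyp1a in their names and read −0.312, 0.0237 and −0.0015 over both days, so the name is no evidence for either. More neutrophils and macrophages as the cause of a rise of this size are argued against. The other 20 markers had a median of 0.0516 (SD 0.523) over both days, with 12 higher and 8 lower and 1 called, against a lower bound of 3.05 for the probe set. A smaller increase in some pools is not excluded. The marker list score was 0.336 on TCDD 2 dpa replicate 3 and 0.463 and 0.279 on TCDD 3 dpa replicates 1 and 3. The highest vehicle score was 0.145, and the other TCDD arrays read −0.170, −0.196 and −0.424. Detection of cyp1a transcript stays open, since exposure and cyp1a separate the arrays alike (a gap of 2.65 between the lowest TCDD and the highest vehicle array). No probe sequence was examined.

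TCDD 2 dpa replicate 3 lay nearer to TCDD 3 dpa replicates 1 and 3 than to its own group. A hybridisation batch shared with those replicates cannot be decided from the control level. The control mean was −0.115 on this array and −0.122 and −0.103 for the rest of its group. It was −0.068 and −0.076 on TCDD 3 dpa replicates 1 and 3, so the level does not set the groups apart. An exchange of day labels with TCDD 3 dpa replicate 2 may explain it: the mean distance within both TCDD groups would be 0.432 against 0.553 as labelled, the lowest of 10 arrangements, with 0.526 next. Both arrays were picked from these same distances, so the lower value restates the pattern and is no separate support for an exchange. Along the vehicle day difference, however, the first array leaned to −0.125, beside −0.268 and −0.128 for the rest of its group, and the second to 0.347, toward 3 dpa. The vehicle day difference called no probe set, so the lean does not decide it. The hybridisation control mean of TCDD 3 dpa replicate 2 was 0.344, near the vehicle 3 dpa arrays (0.260 to 0.292). Every 2 dpa array read lower (−0.143 to −0.0125), which goes against the exchange. As TCDD 3 dpa replicates 1 and 3 also read low, this level does not follow the day and does not decide it either. Differences between pools were not tested.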

How the results depend on the processing

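The hybridisation block, the removal of both arrays that stand apart, the mean of both days, log2(value + 0.1), the removal of probe sets with a median below 1, the removal of the mpx probe set and the alternatives of the lists between days in TCDD were chosen after the data were seen; the other alternatives were planned. Signal over background cannot be had from ratios, so it sets no limit that can be given here. A filter at log2 above 6 cannot be run on centred ratios and was not run, the absence of a filter equals the values reported, the fit of the compared groups alone was not run for the difference of effects, and the unmoderated test was run for pairs of groups only. Where no cause is named, the cause was not tested.

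Of 122 named gene calls, 117 kept their direction and call with quantile normalization, 117 with centred arrays, 110 with trend and robust settings, 111 with the replicate number as a block, 61 with the hybridisation block and 104 without both arrays, and 0 reversed in these. Of 40 values from other probe sets of a called gene, 10 were called in the same direction, 23 were not called and 7 reversed. Of 37 list calls 31 were kept with quantile normalization, 37 with the replicate block, 37 with the mean of a gene's probe sets, 37 without the mpx probe set, 25 with the hybridisation block (9 lost, 3 reversed), 26 without both arrays, 2 with an estimated correlation and 6 with fry. With each array left out in turn, 956 of 1464 named gene calls and 384 of 444 list calls were kept. Whether the replicate numbers pair the arrays is not settled. Of 18 pairs with the same number, 7 had a correlation over 0.1, in a range from −0.252 to 0.493 for all 18. Among arrays of other groups, 7 of 12 arrays correlated best with one of their own number.

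Quantile normalization gave 163 calls at 2 dpa (73 higher, 90 lower, 44.8% higher against 56%) and 1168 for the mean. Array weights gave 247 (106 higher, 141 lower), 426 (195 higher, 231 lower) and 1681 at 2 dpa, 3 dpa and for the mean. The replicate block gave 147 at 3 dpa (75 shared with the 89) and 6 lists between days in vehicle. A pseudocount of 16 gave 43 at 3 dpa, where it compresses small ratios. Adjusted p under 0.01 gave 7, 21 and 118, and a 2-fold minimum 209 for the mean. Only the groups compared gave 6 at 3 dpa, with fewer arrays to estimate the spread, and the unmoderated test gave 0 on each day, with fewer degrees of freedom.

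The hybridisation block gave 39 calls at 2 dpa, 217 at 3 dpa (173 higher, 44 lower), 26 between days in vehicle, 15 for the difference of effects and 387 for the mean, and 6 lists between days in vehicle, where the neural list was −0.079, ribosomal proteins 0.074 and oxidative phosphorylation 0.017. At 3 dpa this block leaves 1 TCDD array against 3. Without both arrays 1519 probe sets were called at 3 dpa, 364 between days in TCDD, 60 for the difference and 1362 for the mean, with 1 list between days in vehicle and 5 in TCDD; these arrays were chosen for their distance, so the spread falls by construction. An estimated correlation left 1, 0, 0, 0 and 1 lists (2 dpa, 3 dpa, days in vehicle, days in TCDD, mean), and fry 3, 2, 0, 0 and 3. The correlation of effects between days, 0.793, was 0.955 among called probe sets, which were chosen for large effects, 0.640 by Spearman, 0.498 with the hybridisation block and 0.529 without both arrays.

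The effect on cyp1a at 2 dpa was not past the threshold with trend and robust settings (8.70, adjusted p = 0.0561) or without both arrays (8.80, adjusted p = 0.0827), in a range from 0.000153. Its difference between days, not called, was −0.31 in vehicle with the hybridisation block, and in TCDD −0.16 with quantile normalization, −0.0056 centred, −0.36 with the hybridisation block and −0.46 without both arrays. Other probe sets reversed for mpx (−0.49, −0.043 and −0.0072 at 2 dpa, −0.14 at 3 dpa, −0.31 and −0.0015 for the mean), for sox9b (0.0093) and for tbc1d23 between days in TCDD (−0.15 and −0.18).

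Leaving out 1 array gave 8 to 49 calls at 2 dpa, 28 to 391 at 3 dpa, 0 to 0 between days in vehicle, in TCDD and for the difference, and 296 to 1471 for the mean. Lists ranged from 7 to 12, 6 to 13, 1 to 5, 1 to 3 and 7 to 16 (2 dpa, 3 dpa, days in vehicle, days in TCDD, mean), the correlation of effects from 0.621 to 0.806, and cyp1a from 7.20 to 9.53 at 2 dpa and 7.21 to 8.51 at 3 dpa. List medians ranged from −0.0021 to 0.093 for the neural list at 2 dpa, and between days in vehicle from −0.014 to 0.066 for it and from −0.23 to 0.0098 for ribosomal proteins, and between days in TCDD from −0.017 to 0.33 for muscle markers. The cyp1a difference ranged from −0.72 to 1.61 in vehicle, −0.36 to 0.20 in TCDD and −1.61 to 0.72 for the difference of effects.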

Other observations

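The mean of both days and the count of splits for lists between days in TCDD fins were chosen after the results were seen, and the other splits of the arrays were planned.

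Signalling lists that held few called genes are given as medians of the mean TCDD effect. The 18 FGF genes had a median of 0.02 and a mean of −0.08 (camera adjusted p = 0.83), with the ligand gene fgf3 (−0.55) and the receptor gene fgfr2 (−1.08) lower, kept for 8 and 3 of the 12 arrays left out. The 9 Hedgehog genes had a median of 0.07 (adjusted p = 0.627) with the transcription factor gene gli3 (−0.45) lower (kept for 6 of 12), and the 21 Notch genes a median of 0.07 (adjusted p = 0.104) with the hairy-related gene her9 (0.79) higher (kept for 5 of 12). The 32 heat shock and unfolded protein genes had a median of −0.07 and a mean of 0.04 (adjusted p = 0.808), with hspb1 and the disulfide isomerase gene pdia3 (−0.72) lower and the stress response gene atf4a (0.53) higher, kept for 12, 5 and 8 of 12 (for atf4a 1 of the 8 at an adjusted p that rounds to 0.05). The 21 inflammation genes had a median of 0.01 and a mean of −0.06 (adjusted p = 0.83), with the chemokine receptor gene cxcr4a (−0.68) lower (kept for 9 of 12). With the hybridisation level as a block the calls of fgfr2 (0.152, in a range from 0.0159), gli3 (0.0927, from 0.0149), her9 (0.107, from 0.0141), pdia3 (0.15, from 0.0183), atf4a (0.1, from 0.00925) and cxcr4a (0.0907, from 0.00544) ended. Another fgfr2 probe set read −0.10 (adjusted p = 0.54). The NRF2 list had a median of 0.17 (adjusted p = 0.0509), the AHR pathway components 0.12 (adjusted p = 0.0712) and the neural markers 0.04 (adjusted p = 0.0712).

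Markers of other tissues and metabolic lists had small medians, though some held genes that changed. The 17 red blood cell markers had a median of 0.04 (adjusted p = 0.169), the 14 endothelial markers 0.09 (adjusted p = 0.169), the 38 liver, gut and yolk markers 0.03 with a mean of −0.05 (adjusted p = 0.8) and the 16 notochord markers 0.06 with a mean of −0.12 (adjusted p = 0.872). The 10 cholesterol synthesis genes had a median of −0.02 with a mean of 0.05 (adjusted p = 0.808) and the 20 glycolysis genes a median of 0.07 (adjusted p = 0.169). The liver, gut and yolk list and the notochord list each held 1 gene called lower. Their fry adjusted p for change in either direction was 0.000233 and 0.00267, and that of the red blood cell list 0.0231. The endothelial, cholesterol and glycolysis lists were not past the threshold in it.

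For the mean of both days, 1 of 100 relabellings of the arrays within each day, drawn from 200, gave as many called probe sets, the real one (775), and the highest other gave 3. This argues against a random division of the arrays for this count, but 1 of 100 is the smallest share that these draws can give. A difference between samples that follows the exposure is not tested by it. For the gene lists of the mean 10 of 100 gave as many (10 real, highest other 13), so chance is not excluded for the number of lists. For the difference of effects all 100 gave as many as the real 0, and the highest other gave 775, from the relabelling that exchanges the exposures on 1 day and so turns the mean effect into a difference.

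Each comparison of 3 arrays with 3 has 10 splits, too few for a share under 0.05. The real count and the highest other were 25 and 0 at 2 dpa and 89 and 62 at 3 dpa. They were 0 and 20 between days in vehicle and 0 and 1082 between days in TCDD. For lists they were 11 and 9 at 2 dpa, 10 and 12 at 3 dpa, 3 and 7 between days in vehicle and 3 and 8 between days in TCDD. The number of splits with a result as large, the real one included, was 1, 1, 10 and 10 for probe sets and 1, 3, 10 and 10 for lists in the same order. The split with 1082 calls sets TCDD 2 dpa replicates 1 and 2 and TCDD 3 dpa replicate 2 against the other TCDD arrays, which points to a structure of the samples that the day labels do not follow. The split with 62 sets vehicle 3 dpa replicates 1 and 2 and TCDD 3 dpa replicate 1 against the rest.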
